A study of Mus musculus with 15 samples.

How the data were processed

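Small RNA libraries were made from the brains of 15 mice, 5 in each of 3 groups (sham operation, intracerebral haemorrhage, and haemorrhage treated with Buyang Huanwu decoction), and the deposited tables give 1 column of read counts per mature miRNA for each library. Per the labels' protocols, the tissue was the basal ganglia on the side of the haemorrhage at day 14, after saline perfusion, and libraries were made with the NEBNext small RNA kit and selected by size. The labels name an exosome pellet as the source of the RNA in the same protocol, so whether whole tissue or vesicles were profiled is not settled here. Their housing text speaks of rats in 1 place and of mice in the rest, and the organism given is mouse.

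Per the submitters' processing notes, the authors used cutadapt, Bowtie and edgeR, for which no versions are given in the sources used here. The build named in the same notes is hg38, a human assembly, while the samples are mouse and the names in the tables are mouse miRNA names. How reads matching several loci were assigned is not given in the sources used here. The deposited values are whole-number counts that were not normalized, with totals that differ between libraries.

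Names and counts did not line up in the deposited tables. Each of the 15 tables holds 929 count values and 928 names, and the last row has no name. In 15 of 15 tables the first count value equals the library number in the table's own title, a stray heading, so every count stands 1 row below its name. This was tested on names that occur on up to 4 rows, which should carry nearly equal counts. With the names moved down 1 row, 88 of 103 such row pairs (85.4%) had counts within 0.1 on the log2 scale, against 24 (23.3%) as printed. The median correlation between the arms of 1 hairpin was 0.52 with the move and 0.23 as printed, among miRNAs with a mean count of at least 50, and the other moves tested, of up to 4 rows either way, gave lower values of both. As printed, 1 of the 3 rows named miR-9-5p had a mean count of 19.8, and after the move all 3 had close to 771969. All values below use the moved names. The counts assigned here to miR-155-5p stand beside miR-223-5p in the tables, those of miR-142a-3p beside miR-384-5p, those of miR-10a-5p beside miR-181d-5p and those of miR-147-3p beside miR-135b-3p.

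Of the 683 distinct names, 76 occur on more than 1 row, taken here to be 1 row per locus encoding the same mature miRNA, since most of the row pairs tested above had nearly equal counts. The row with the highest total was kept for each name. Rows as deposited had been planned as the main setting and became the alternative when the repeats were seen, before any groups were compared. Another 34 names share their reads with a different name, with counts within 1% in every library, and values of such pairs are uncertain as to which name they belong to. Total counts per library were 4684611 to 9860236 after repeats were removed, which kept 66.6 to 74.8% of the counts over all rows.

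Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test with robust estimation, TMM scaling, filterByExpr by group) under R 4.3.3, with all 15 libraries in 1 fit and no covariates. After the filter 652 miRNAs were tested in each of the 3 comparisons, and p-values were adjusted by the Benjamini-Hochberg method. A miRNA is called changed when its adjusted p is under 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and the F statistic, and abundances are CPM (counts scaled for depth) on TMM-scaled library sizes, computed from the deposited counts. On simulated counts with 200 of 652 miRNAs changed, the test recovered 79.1% of 2-fold and 44.8% of 1.5-fold changes for ICH versus sham, with 4.58% false calls. The shares recovered for BYHWD versus ICH were 73.1% of 2-fold and 34.3% of 1.5-fold changes, and for BYHWD versus sham 76.1% and 43.3%. With fewer changed miRNAs than simulated the adjustment is stricter, so the real recovery is lower where few miRNAs change. Each comparison had 1 simulated set, with the same spread of a miRNA in every group and no libraries that stand apart. The order of recovery between comparisons may therefore differ in the real data.

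Before the data were examined, 27 lists of miRNAs were fixed for cell types, genomic clusters and seed families. The 25 with at least 3 tested members were tested with limma's camera (version 3.58.1) on log2 CPM with a prior count of 2, with a correlation between members estimated from the data, and adjusted over the lists within each comparison. The miRNAs named were chosen by a rule fixed at the same time. It takes called miRNAs with a mean of at least 10 CPM by size of change (up to 10 in each direction), the 10 with the smallest p where fewer than 10 are called, the 4 most abundant members of each list with a called member, the 2 most abundant members of 6 lists for other cell types, and the 10 most abundant miRNAs. Called miRNAs below 10 CPM are named as well, chosen after their values were seen. Reversal was examined as the covariance of log2 fold changes between comparisons, set against 100 simulated sets of unchanged groups and against fits with the ICH libraries divided into sets of 2 and 3. Library measures were compared with an exact two-sided permutation test over 252 arrangements.

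Alternatives were median-ratio, upper-quartile and no scaling, no filter and a filter at 10 CPM, DESeq2 1.42.0, limma-voom, fits of 2 groups only, the replicate number as a block, the 5 most abundant miRNAs left out, rows as deposited, and each library left out in turn. Those added after seeing the data were the omission of sham 4 and sham 5 together, limma-voom with sample quality weights, and names sharing reads kept once. No library was a duplicate of another, as the lowest chi-square per degree of freedom over 105 pairs was 112. Hairpin positions come from GENCODE M21 (GRCm38). The precision of a count of few reads is limited by counting error as well as by animals, and PCR copies cannot be told from separate molecules.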

Results

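MicroRNAs were profiled by small RNA sequencing in the basal ganglia of mice 14 days after intracerebral haemorrhage (ICH), a bleed into the brain tissue. The groups were 5 mice with a sham operation and 5 with ICH, both given water by gavage, and 5 with ICH given Buyang Huanwu decoction (BYHWD), a herbal mixture used in traditional Chinese medicine, at 6.19 g/kg daily for 14 days. The libraries held 4684611 to 9860236 counts with 1 row per miRNA, and between 674 and 682 miRNAs had at least 1 read. The mice are separate animals per the labels, so the spread between libraries includes that between animals.

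The most abundant miRNA was miR-9-5p, a brain-enriched miRNA, at a mean of 102070 CPM over all 15 libraries. It was followed by miR-30a-5p (59019 CPM), let-7f-5p (50061 CPM), miR-127-3p of the imprinted Dlk1-Dio3 region (48436 CPM) and let-7g-5p (45919 CPM). The next were miR-26a-5p (35383 CPM), miR-7a-5p (34809 CPM), miR-99a-5p (33562 CPM), let-7i-5p (32370 CPM) and miR-101a-3p (28989 CPM). The means of miR-30a-5p and miR-101a-3p were raised by sham 4 and sham 5, and over the other 13 libraries miR-30a-5p averaged 41821 CPM, below let-7f-5p, miR-127-3p and let-7g-5p. In these libraries miR-101a-3p stood at 137472 and 88982 CPM, against at most 20621 CPM in the other 13.

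The comparison of ICH with sham asks which miRNAs differ 14 days after the bleed. Here 5 miRNAs rose and none fell. The largest group among them belongs to leukocytes and to the inflammatory response. MiR-155-5p, induced in activated macrophages and microglia, went from 15.6 ± 4.68 CPM in sham to 65.0 ± 13.9 CPM in ICH (mean ± SD, n = 5 each), a 4.18-fold difference (log2 2.06, SE 0.23, edgeR adjusted p = 6.26e-05). MiR-142a-3p, made in blood-forming lineages, rose 3.25-fold from 17.7 ± 5.13 to 57.6 ± 16.3 CPM (log2 1.70, SE 0.29, edgeR adjusted p = 0.00395). MiR-147-3p, induced in stimulated macrophages, rose 8.39-fold (log2 3.07, SE 0.41, edgeR adjusted p = 0.000328), but from very few reads, with 15 counts summed over the sham libraries and 157 over the ICH libraries. All 5 ICH libraries lay above all 5 sham libraries for each of these miRNAs.

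The other called miRNAs were both arms of miR-10a, which is encoded in the Hoxb gene cluster. MiR-10a-5p rose 5.30-fold from 128 ± 34.6 to 677 ± 471 CPM (log2 2.41, SE 0.43, edgeR adjusted p = 0.00666), with all 5 ICH libraries above all sham libraries. Its ICH mean was raised by ICH 3 at 1513 CPM, and with a choroid plexus score in the fit the log2 fold change was 2.07 (SE 0.45, edgeR adjusted p = 0.0575). MiR-10a-3p had 10 counts in sham and 97 in ICH (log2 2.97, SE 0.63, edgeR adjusted p = 0.0296). Its Hox-cluster relative miR-10b-5p was at 84.4 ± 38.1 CPM in sham and 88.3 ± 12.9 CPM in ICH (log2 0.07, SE 0.27, edgeR adjusted p = 0.904). MiR-147-3p and miR-10a-3p averaged below 10 CPM and were named after their values were seen.

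On GRCm38, the miR-155 hairpin lies on chromosome 16 at 84714140 to 84714204, plus strand, in an exon of the noncoding gene Mir155hg. The miR-142a hairpin is on chromosome 11 at 87756864 to 87756927, plus strand, in an intron of Mir142hg. The miR-10a hairpin is on chromosome 11 at 96317165 to 96317274, plus strand, with no annotated host on that strand. The miR-147 hairpin, on chromosome 2 at 122640803 to 122640881, plus strand, overlaps an exon of the protein-coding gene AA467197. MiR-21a is on chromosome 11 at 86584067 to 86584158, minus strand, in an exon of Vmp1.

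In the list of myeloid and leukocyte miRNAs, which counts both arms of a hairpin as members, 8 of 9 tested members had positive log2 fold changes (median 1.67). Of these, 3 were called over all miRNAs and 7 when adjusted over the list alone. Besides those above, miR-142a-5p stood at 117 ± 46.2 CPM in sham and 266 ± 57.3 CPM in ICH (log2 1.19, SE 0.30, edgeR adjusted p = 0.0687), while the lymphocyte miRNA miR-150-5p stood at 207 ± 46.8 and 226 ± 29.4 CPM (edgeR adjusted p = 0.709). In the list of miRNAs induced by NF-kB and injury, 2 of 8 were called and 7 when adjusted over the list alone (median 1.03). The 2 lists share miR-155 and miR-147. MiR-21a-5p, which is raised in many injured tissues, was at 14366 ± 2634 CPM in sham and 27398 ± 7690.4 CPM in ICH, just short of the threshold (log2 0.93, SE 0.21, edgeR adjusted p = 0.0502). MiR-146a-5p, an NF-kB target, had a log2 fold change of 0.85 (SE 0.31, edgeR adjusted p = 0.126), and miR-146b-5p one of -0.30 (SE 0.33), which was 0.59 without sham 4 and sham 5. As sets, neither list passed with an estimated correlation (adjusted p = 0.0718 for the myeloid list and adjusted p = 0.0624 for the NF-kB list). Both passed with a preset correlation of 0.01 (adjusted p = 1.26e-07 and adjusted p = 3.47e-08). The correlations estimated from the data were 0.33 and 0.26, far above that preset, so the p-values it gives are too small for these lists. Both lists also passed with fry, another limma test of sets (adjusted p = 0.000953 and adjusted p = 0.000381). Unlike camera, fry does not compare the members with the other miRNAs.

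All 5 tested members of the fibroblast and mesenchymal list (miR-199a, miR-199b and miR-214) had positive values (median 0.93). None was called over all miRNAs and 5 were when adjusted over the list alone (adjusted p = 0.284 for the set with an estimated correlation, 0.000537 with the preset one). MiR-199a-3p, whose mature sequence is shared with miR-199b-3p, stood at 133 ± 22.7 CPM in sham and 253 ± 91.4 CPM in ICH (edgeR adjusted p = 0.0687). Of 90 miRNAs of the Dlk1-Dio3 imprinted cluster, a maternally expressed region active in neurons, 73 had negative values (median -0.22). None of them was called over all miRNAs and 8 were when adjusted over the list alone (adjusted p = 0.0718 for the set with an estimated correlation, 1.14e-07 with the preset one). The lowest p in the cluster among abundant members was that of miR-379-5p, at 4538 ± 1410.3 CPM in sham and 2722 ± 334 CPM in ICH (log2 -0.74, SE 0.19, edgeR adjusted p = 0.0687). It was highest in sham 4 and sham 5, at 6752 and 5077 CPM, and its log2 fold change was -0.42 without them. The X-linked cluster of miR-322, miR-503, miR-351, miR-542 and miR-450 had a median of 0.31 and 3 of 8 members past the threshold when adjusted over the list alone (adjusted p = 0.21 for the set with an estimated correlation, 0.00662 with the preset one). Also passing with the preset correlation were the Hox cluster list (adjusted p = 0.004, and 0.135 with an estimated one) and the miR-17-92 list (adjusted p = 0.004, and 0.299 with an estimated one). The estimated correlation was 0.77 for the fibroblast list, 0.06 for the Dlk1-Dio3 cluster and 0.15 for the X-linked cluster. It was 0.31 for the Hox list and 0.17 for the miR-17-92 list, so the preset p-values are too small here as well. With fry the adjusted p was 0.0371 for the fibroblast list, 0.00825 for the Dlk1-Dio3 cluster and 0.0113 for the X-linked cluster. By the same test it was 0.00628 for the Hox list and 0.0387 for each of the miR-17-92 and let-7 lists.

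Markers of other cell types gave no calls. The erythroid miRNA miR-451a was at 119 ± 89.1 CPM in sham and 70.1 ± 28.3 CPM in ICH (edgeR adjusted p = 0.453), and the erythroid list had 7 of 7 members below 0 (median -0.15, set adjusted p = 0.782). These members are not independent, as miR-486a and miR-486b share their reads on both arms. For endothelial and mural cells, miR-126a-3p had a log2 fold change of -0.18 (SE 0.15) and miR-143-3p one of 0.04 (SE 0.24). The oligodendrocyte miRNAs miR-219a-2-3p and miR-338-5p had values of -0.53 (SE 0.31) and 0.16 (SE 0.13), and miR-219a-2-3p, at 23192 and 19415 CPM in sham 4 and sham 5, had 0.30 without these libraries. The oligodendrocyte list had 4 of 5 members above 0 (median 0.38, set adjusted p = 0.299, and 0.0434 with fry). None of its members passed when adjusted over the list alone. For choroid plexus and epithelium, miR-204-5p had 0.46 (SE 0.36) and miR-200a-3p 0.34 (SE 0.43), and for multiciliated cells miR-34b-5p had -0.02 (SE 0.47) and miR-34c-5p 0.15 (SE 0.42). The neuron and brain-enriched list had a median of -0.22 over 13 members (set adjusted p = 0.672). Of these, 4 were lower when adjusted over the list alone.

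The number of ICH calls depended on the tool and on single libraries. DESeq2 called 20 higher and 27 lower, the fit without sham 3 called 14 higher and 17 lower, that without sham 2 called 6 and 6, and that without ICH 4 called 11 higher. Without sham 4 and sham 5, which stood apart from all other libraries, 6 were higher and 1 lower, of which 3 were among the 5 above (miR-155-5p, miR-142a-3p and miR-147-3p), and miR-146a-5p was then called (log2 1.62, SE 0.17, edgeR adjusted p = 3.1e-05) while miR-10a-5p (log2 2.53, edgeR adjusted p = 0.0623) and miR-10a-3p (log2 3.00, edgeR adjusted p = 0.0793) were not.

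**Figure D1:**
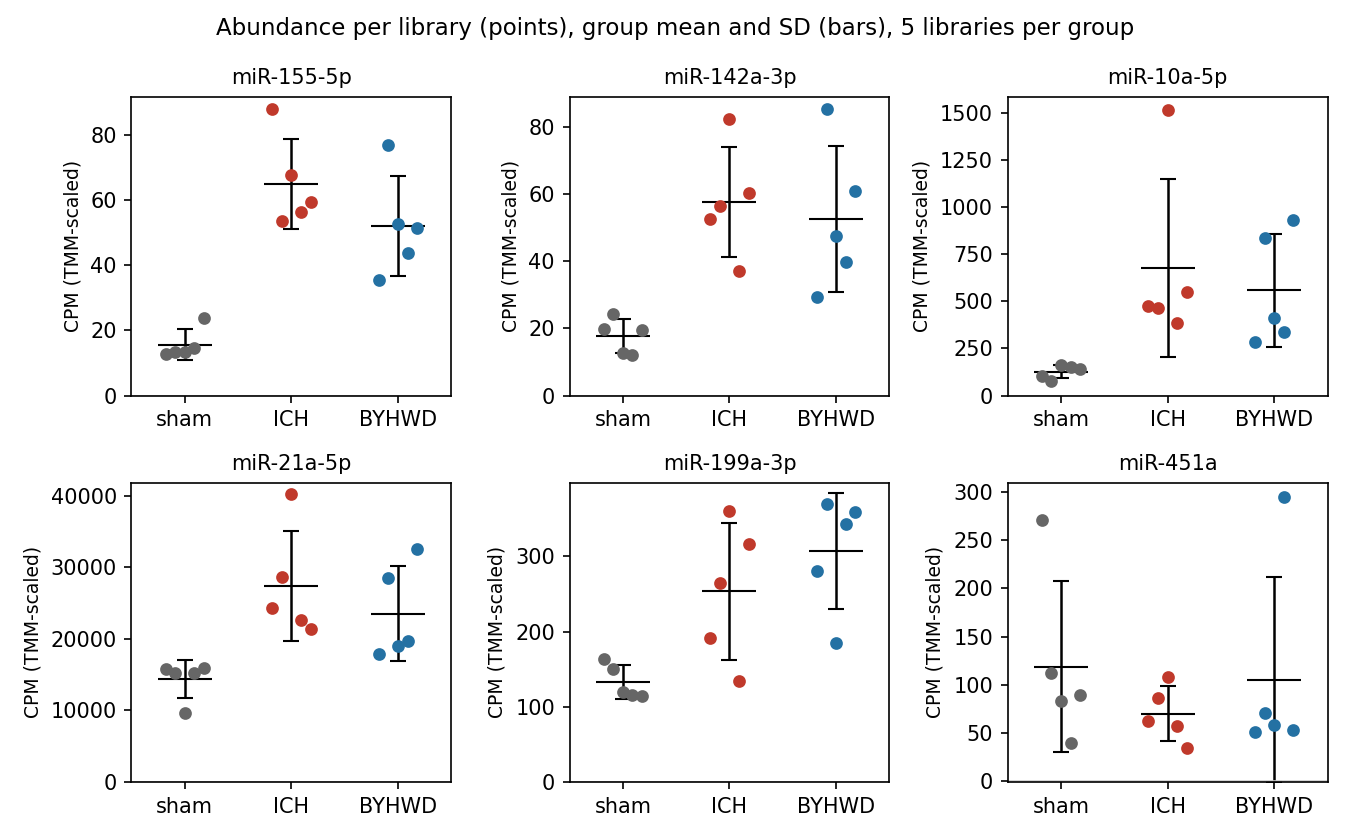
Abundance of 6 miRNAs in each library on a linear axis of TMM-scaled CPM, with 5 points per group for sham, ICH and BYHWD, a horizontal bar at the mean and whiskers of 1 SD. The ICH and BYHWD libraries lie above all sham libraries for miR-155-5p, miR-142a-3p and miR-10a-5p, while miR-451a overlaps between the groups and its highest values are in sham 1 and BYHWD 4.

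The comparison of BYHWD with ICH asks which miRNAs the decoction altered in mice with haemorrhage. No miRNA was called by edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 edgeR gave 31 of 652 (4.75%), where 32.6 would be found by chance, DESeq2 gave 32 and limma-voom 28, and the lowest adjusted p was 0.916. The miRNAs called higher in ICH with all libraries were near their ICH levels in treated mice. MiR-155-5p was at 52.0 ± 15.4 CPM in BYHWD, with a log2 difference from ICH of -0.32 and an interval of 2 SE from -0.75 to 0.12, whereas a return to the sham level would need -2.06. The interval for miR-142a-3p was -0.68 to 0.42, where -1.70 would be needed, and that for miR-10a-5p was -1.08 to 0.53, where -2.41 would be needed.

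Among abundant miRNAs, those with the smallest p included the paralogs miR-7a-5p and miR-7b-5p, brain miRNAs abundant in neuroendocrine tissue. MiR-7a-5p was at 23598 ± 4430.4 CPM in ICH and 45410 ± 29622 CPM in BYHWD (log2 0.94, SE 0.36, edgeR adjusted p = 0.916). The high mean in BYHWD rests on BYHWD 4 and BYHWD 5, at 55395 and 92978 CPM, beside 21321 to 30587 CPM in the other 3. MiR-7b-5p had a log2 difference of 1.03 (SE 0.37) and miR-298-5p one of 0.75 (SE 0.28). Members of the Dlk1-Dio3 cluster were also among them, with miR-758-3p at 0.72 (SE 0.26), miR-770-5p at 0.66 (SE 0.25) and miR-380-3p at 0.43 (SE 0.17). MiR-296-3p had 0.61 (SE 0.21) and miR-760-3p 0.41 (SE 0.16), and values below 0 were found for miR-375-3p, an islet and neuroendocrine miRNA (-0.42, SE 0.15), and miR-3086-5p (-0.67, SE 0.25). None of these passed (edgeR adjusted p = 0.916 for each). No list passed under any test of sets, and the lowest adjusted p with an estimated correlation was 0.964. The medians were -0.13 for the myeloid list, -0.20 for the NF-kB list, 0.28 for the fibroblast list, 0.12 for the erythroid list and 0.09 for the Dlk1-Dio3 cluster. MiR-451a had a log2 difference of 0.59 (SE 0.55), set by BYHWD 4 at 295 CPM. MiR-142a-5p (-0.27, SE 0.29), miR-126a-3p (-0.01, SE 0.15), miR-143-3p (0.15, SE 0.24), miR-219a-2-3p (-0.16, SE 0.31), miR-204-5p (0.19, SE 0.36) and miR-34c-5p (0.04, SE 0.42) each lay within 1 SE of 0.

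Whether BYHWD moved the ICH profile back towards sham was examined across all 652 miRNAs. The log2 fold changes of ICH against sham and of BYHWD against ICH had a correlation of -0.30 across miRNAs, which are not independent replicates, and a covariance of -0.0402. Both comparisons contain the ICH libraries, and simulated unchanged groups gave a covariance of -0.0378 ± 0.00491 (SD over 100 sets), a difference of -0.00238. Their correlation was -0.488 ± 0.0431. These sets give each miRNA the same spread in all groups. Sample quality weights, lower for libraries that deviate more, were 0.937 to 3.27 in ICH and 0.334 to 0.919 in sham. The simulated values may therefore be too negative, and the small difference does not exclude a reversal. With separate ICH libraries in each comparison, the covariance had a median of -0.011 over 20 divisions, from -0.0298 to 0.027. The correlation then had a median of -0.073, from -0.22 to 0.12. No miRNA passed in both comparisons with opposite signs. At an unadjusted p under 0.05 there were 10, among them miR-375-3p, miR-298-5p and miR-760-3p, where the simulated sets gave 6.06 ± 2.66.

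**Figure D2:**
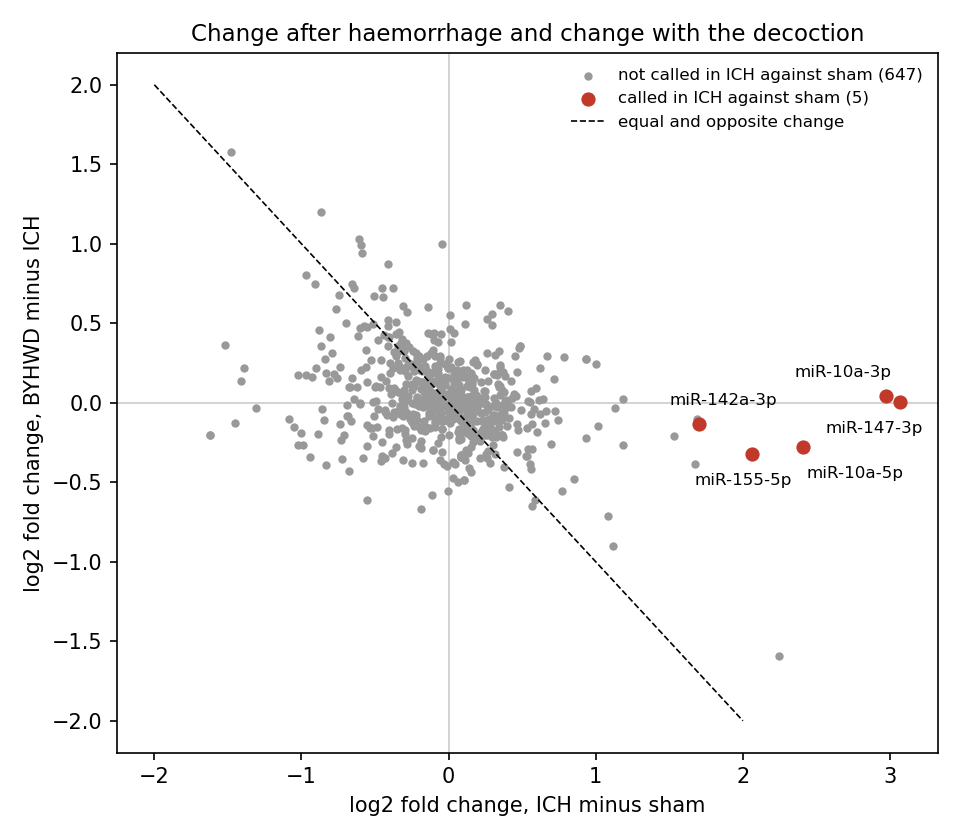
Log2 fold change of ICH minus sham on the horizontal axis against that of BYHWD minus ICH on the vertical axis, 1 point for each of 652 miRNAs, with the 5 called in ICH against sham in red and a dashed line where changes would be equal and opposite. The 5 called miRNAs lie between 1.70 and 3.07 on the horizontal axis and between -0.32 and 0.04 on the vertical axis, away from the dashed line.

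The comparison of BYHWD with sham asks how far treated mice were from mice without a haemorrhage. Here 13 miRNAs rose and 2 fell. All 5 miRNAs that rose in ICH rose here too. MiR-155-5p was 3.35-fold above sham (log2 1.75, SE 0.23), miR-147-3p 8.43-fold (log2 3.08, SE 0.41), miR-142a-3p 2.96-fold (log2 1.57, SE 0.29) and miR-10a-5p 4.37-fold (log2 2.13, SE 0.42), with edgeR adjusted p-values from 0.000353 to 0.0117. MiR-10a-3p had a log2 fold change of 3.01 (edgeR adjusted p = 0.0152). All 13 higher miRNAs lay above all sham libraries in 5 of 5 BYHWD libraries, and both lower ones below. For miR-21a-3p this rests on few reads, with overlapping raw counts of 6 to 14 per sham library and 10 to 25 per BYHWD library.

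Of the 5 mesenchymal miRNAs 3 were called, 2 of them with the same reads, and the set did not pass with an estimated correlation (adjusted p = 0.205). MiR-199a-3p and miR-199b-3p, which share their reads, went from 133 ± 22.7 CPM in sham to 307 ± 77.0 CPM (log2 1.21, SE 0.25, edgeR adjusted p = 0.0117), and miR-199b-5p from 18.3 ± 3.97 to 38.7 ± 12.96 CPM (log2 1.07, SE 0.27, edgeR adjusted p = 0.0474). All 5 members of this list passed when adjusted over the list alone. MiR-374b-5p and miR-374c-5p, from opposite strands of 1 locus in an intron of Ftx and with shared reads, rose from 160 ± 31.9 to 286 ± 43.3 CPM (log2 0.84, SE 0.17, edgeR adjusted p = 0.0117). From the X-linked cluster, miR-450a-5p (log2 0.69, edgeR adjusted p = 0.0377) and miR-450b-5p (log2 0.68, edgeR adjusted p = 0.0474) rose, 2 of 8 members. Neither was called without sham 4 and sham 5 (edgeR adjusted p = 0.183 and 0.0975). MiR-542-3p, over 2-fold higher in sham 4 and sham 5 than in the other sham libraries, had -1.26 (SE 0.51), and 0.25 without these libraries. Adjusted over the list alone, 3 members of this cluster were higher and 1 lower (adjusted p = 0.301 for the set with an estimated correlation). MiR-21a-3p rose (log2 1.10, edgeR adjusted p = 0.0474), and miR-21a-5p did not pass (log2 0.71, edgeR adjusted p = 0.0933). The call of miR-21a-3p was lost in 21 of 28 alternative settings, among them the fit without sham 4 and sham 5 (edgeR adjusted p = 0.117). MiR-21a-3p and miR-450b-5p averaged below 10 CPM. The miRNAs that fell were miR-379-5p of the Dlk1-Dio3 cluster (log2 -0.87, SE 0.19, edgeR adjusted p = 0.0178) and miR-31-5p (log2 -1.28, SE 0.32, edgeR adjusted p = 0.0474). Without sham 4 and sham 5, in which miR-31-5p was over 2-fold higher than in the other sham libraries, neither passed (log2 -0.55, edgeR adjusted p = 0.0975, and log2 -0.58, edgeR adjusted p = 0.242). In the same cluster miR-127-3p (0.05), miR-381-3p (0.12), miR-434-5p (-0.13) and miR-300-3p (-0.03) did not pass, and adjusted over the list alone miR-379-5p was again the 1 member of 90 called. For the myeloid list 3 of 9 members were called and 6 when adjusted over the list alone, and for the NF-kB list 3 of 8 and 5 (adjusted p = 0.205 for each set with an estimated correlation).

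The ICH and BYHWD calls share all 5 higher miRNAs, where independent lists would share 0.0997, a value that leaves out the sham libraries common to both comparisons. Simulated unchanged groups shared 0, which sets no level for lists of this length. The covariance of the log2 fold changes was 0.196 (correlation 0.84 across miRNAs), against 0.0394 in simulated unchanged groups (correlation 0.504 ± 0.0449), a difference of 0.156. With separate sham libraries it was 0.139 at the median, from 0.0594 to 0.172 (correlation 0.46, from 0.19 to 0.66). The simulated groups hold no libraries that stand apart together as sham 4 and sham 5 do. Divisions with sham 4 and sham 5 on opposite sides keep that difference in both comparisons. How much of the covariance it makes was not tested. The count of 15 was 52 with DESeq2 (22 higher and 30 lower), 23 with rows as deposited, 9 with the BYHWD and sham libraries alone and 7 without sham 4 and sham 5. Of the 15, those still called in this last fit were miR-155-5p, miR-147-3p, miR-374b-5p and miR-374c-5p, while miR-142a-3p (edgeR adjusted p = 0.0526), miR-10a-5p, miR-10a-3p and miR-199a-3p (edgeR adjusted p = 0.0975 for each) were among those that did not pass. Leaving out 1 library gave 2 without sham 4, 5 without sham 5, 3 without BYHWD 5, 8 without BYHWD 2, 9 without BYHWD 4, 44 without sham 1 and 54 without sham 3. Upper-quartile scaling gave 9 higher and 3 lower.

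**Figure D3:**
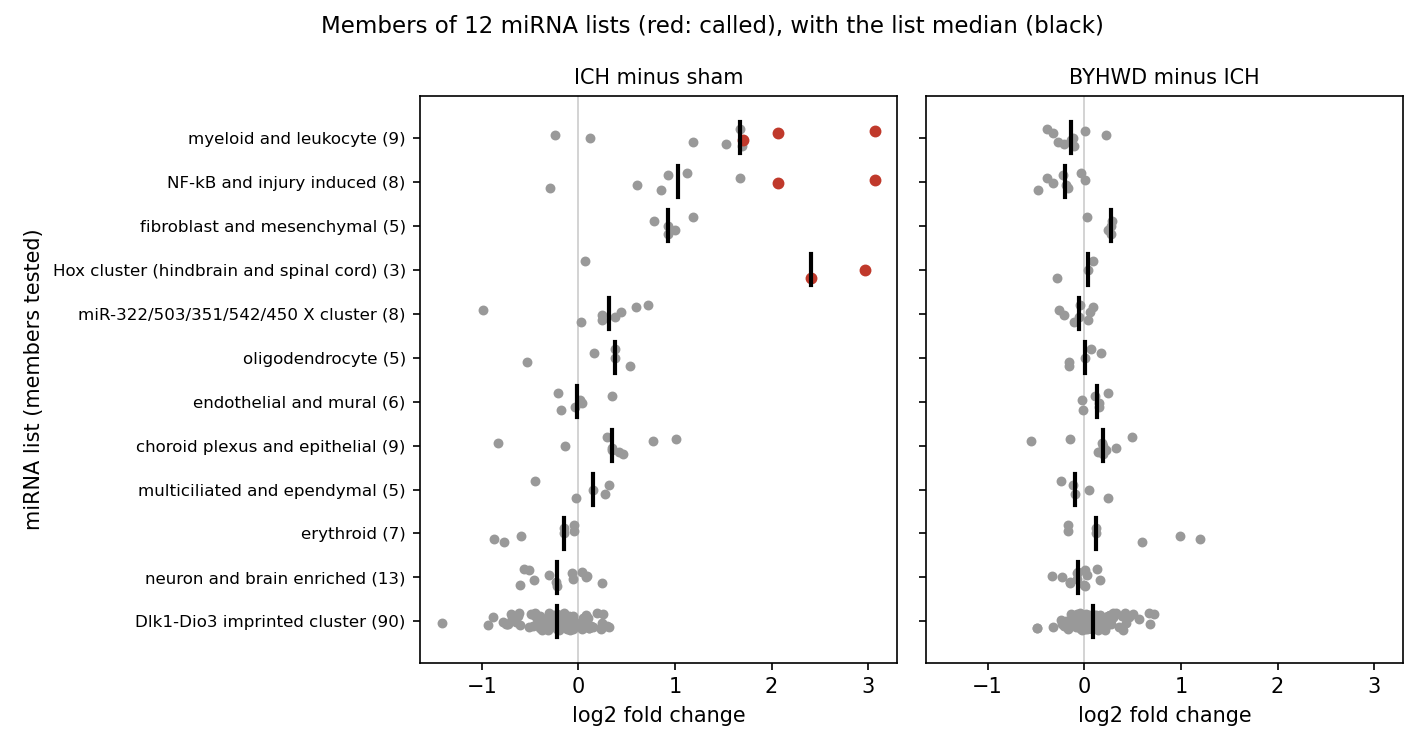
Log2 fold changes of the members of 12 of the 27 miRNA lists, ICH minus sham on the left and BYHWD minus ICH on the right, with 1 point per miRNA, red points for called miRNAs and a black bar at the list median. The myeloid and NF-kB lists have medians of 1.67 and 1.03 on the left and of -0.13 and -0.20 on the right, where no point is red.

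No library measure passed, and a single one of the 12 tests could not, since its adjusted p cannot go below 0.0952. For total counts the p was 0.437 between ICH and sham (exact two-sided permutation test), and the lowest adjusted p over 4 measures and 3 comparisons was 0.593 (exact two-sided permutation test, 12 tests). The share of the most abundant miRNA was 11.4 ± 0.6% in sham and 10.7 ± 0.439% in ICH (exact permutation p = 0.0714). This measure mixes miRNAs, as the most abundant was miR-30a-5p in sham 4 and sham 5, miR-7a-5p in BYHWD 5 and miR-9-5p elsewhere. The share of the 10 most abundant was 50.0 ± 5.1% in sham, 47.1 ± 0.919% in ICH and 48.2 ± 1.13% in BYHWD. In sham 4 and sham 5 it was 56.0% and 54.6%, above the other 13 libraries, and 674 miRNAs had a read in each, the fewest of all.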

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

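The tests of sequencing depth, of residual blood, of the weight of sham 4 and sham 5 and of hindbrain tissue were chosen only after the result was seen. The single values that stood apart in their group of 5 came from 6 of the 189 groups of values examined, where chance alone flags about 1 in 20.

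MiR-10a-5p in ICH 3 stood at 1513 CPM, against 386 to 547 CPM in the other ICH libraries. MiR-143-3p, a smooth muscle miRNA, was at 33558 CPM in BYHWD 1 and at most 20112 CPM in the others of that group. MiR-155-5p in sham 5 was at 23.9 CPM, above 12.7 to 14.7 CPM in the other sham libraries and below every ICH library. MiR-21a-5p in sham 3 was at 9686 CPM, where the other sham libraries lay between 15223 and 15928 CPM. MiR-451a in BYHWD 4 was at 295 CPM, with the others at 50.8 to 70.6 CPM. The share of the most abundant miRNA in sham 5, there miR-30a-5p, was 12.5%, against at most 11.3% in the other sham libraries.

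Sham 4 and sham 5 stood apart from sham 1, 2 and 3. On the first principal component (26.8% of the variance) they lay at -14.8 and -12.1, with the other 13 libraries between -1.88 and 6.37, and 54 miRNAs were over 2-fold higher (among them miR-101a-3p, miR-30e-5p and miR-542-3p) and 13 over 2-fold lower in them than in the other sham libraries. The tables argue against depth, since the totals of both (2 of 2) lie inside the range of the other 13. Base composition stays open, as the rank correlation with the GC percent of the hairpin arm was -0.13 over 595 of 652 miRNAs, inside the range of -0.18 to 0.16 given by the 78 pairs of other libraries and short of the 0.3 that would point to it. A difference between library batches or between animals may account for it and was not tested, as the labels give neither.

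The leukocyte and injury lists hold 14 members, with both arms of a hairpin counted separately. Of these, 12 had positive log2 fold changes in ICH against sham (median 1.16) and 3 were called over all miRNAs. Neither list passed as a set with an estimated correlation (adjusted p = 0.0718 and adjusted p = 0.0624). More residual blood in ICH was taken to raise the erythroid miRNAs by at least 1 on the log2 scale, a level set after the result was seen. Their score differed by -0.27 (SE 0.20), which argues against more red cells in the ICH tissue. It does not measure blood leukocytes left without red cells, so these are not excluded. Sham 4 and sham 5 do not make the difference, as the median was 1.38 without them. What stays open is a larger number of leukocytes or activated microglia in the tissue against a change within resident cells, which counts from bulk RNA cannot separate, and no test here bears on that choice. Whether the RNA came from whole tissue or from vesicles is not settled either.

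MiR-10a-5p was higher in ICH than in sham. Tissue from the hindbrain or spinal cord, where the Hox clusters are active, would carry miR-10b-5p as well, and its log2 fold change was 0.067 (SE 0.27). Choroid plexus in the dissected piece was tested with a score of miR-204-5p and miR-211-5p in the fit. The log2 fold change went from 2.41 (SE 0.43) to 2.07 (SE 0.45, edgeR unadjusted p = 0.000353). The call ended (edgeR adjusted p = 0.00666 before and 0.0575 after) because the estimate fell slightly and its error grew. As most of the fold change was kept, the values argue against choroid plexus, as this score measures it, as the main source. A smaller part is not excluded. The score itself differed by 0.48 (SE 0.52) between the groups, and within groups it had a Pearson r of 0.28 with miR-10a-5p (permutation p = 0.307) and a Spearman rho of 0.23 (permutation p = 0.42), with r = 0.26 without the 2 farthest libraries. Cells that enter the lesion or divide there are a biological hypothesis that was not tested.

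Over all miRNAs, 3 of 100 splits of the ICH and sham libraries, the real one included, called at least as many as the real 5. That share is under the 0.05 set beforehand. The highest of the other splits called 8, more than the real one, so chance is not excluded for that count. These splits did not test the lists. Between BYHWD and ICH the real count was 0, which every split reaches by construction (100 of 100, highest other 0), so the splits decide nothing there. Between BYHWD and sham 1 of 100 splits, the real one, called as many as 15, and the highest other called 4.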

How the results depend on the processing

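Counts of called miRNAs against sham moved furthest with DESeq2 and with single sham libraries left out, and by less with other choices. Sham 4 and sham 5 left out together, quality weights and names sharing reads kept once were added after the data were seen. The cause was not tested unless stated.

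For ICH versus sham (5 called), upper-quartile factors gave 10, library size alone 9, the filter at 10 CPM 3 (miR-147-3p and miR-10a-3p are then not tested) and DESeq2 47, with the 5 among them. Leaving out 1 library gave 4 to 31. For BYHWD versus sham (15 called), DESeq2 gave 52, fits of 2 groups only 9, rows as deposited 23 (repeats of 1 miRNA count several times), sham 4 and sham 5 left out 7, limma-voom with quality weights 7 and names sharing reads kept once 9. In this last setting miR-199b-3p and miR-374c-5p, called from the same reads as other names, are not tested. Other calls near the threshold were lost as well, so the count of 15 rests in part on reads counted under 2 names. Leaving out 1 library gave 2 to 54. Of the 27 miRNAs that DESeq2 called lower in ICH, 10 (37.0%) were over 2-fold higher in sham 4 and sham 5 than in the other sham libraries, against 8.28% of all tested. For BYHWD versus ICH every setting gave 0, with 12 to 55 miRNAs at an unadjusted p under 0.05. Library size alone moved the median log2 fold change of all miRNAs in BYHWD versus sham from 0.02 to 0.15, and no other scaling moved a median by over 0.1.

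The labels number the mice 1 to 5 in each group and name no pairing. Of 15 pairs of libraries with the same number, 3 had deviations correlated above 0.1, and 2 of 15 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate block 5 miRNAs were called for ICH versus sham, 0 for BYHWD versus ICH and 9 for BYHWD versus sham, and the reversal covariance was -0.0352.

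The reversal covariance (-0.0402) was -0.0269 with the filter at 10 CPM, -0.0544 without sham 4 and sham 5, and -0.0659 to -0.0325 with 1 library left out, each without a matching simulation. Lists passing for ICH versus sham numbered 0 with an estimated correlation, 7 with the preset one, 9 with fry, 2 with median-ratio factors (the NF-kB list, adjusted p = 0.0348, and the Dlk1-Dio3 cluster), 1 with library size alone (the NF-kB list) and 1 without sham 4 and sham 5 (the NF-kB list, adjusted p = 0.0214). For BYHWD versus sham they numbered 0, 8 with the preset one, 6 with fry and 1 without sham 4 and sham 5 (the NF-kB list). For library measures 0 passed with any library left out, which says nothing about stability, since a single measure could not pass.

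Across 88 named results and their alternatives, 2264 of 2537 values kept direction and side of the threshold, 140 lost the call, 47 gained one and 86 turned sign. MiR-155-5p and miR-147-3p kept their calls against sham in every setting that tested them, for ICH with log2 fold changes of 1.92 to 2.29 and 2.89 to 3.23. MiR-142a-3p kept it for ICH in all 29 settings. For ICH miR-10a-5p lost it in 1 of 29 settings and miR-10a-3p in 6 of 27, miR-21a-5p gained it in 10, and for BYHWD miR-142a-3p lost it in 2, miR-10a-5p in 4, miR-10a-3p in 5, miR-199a-3p and miR-199b-3p in 5 each, and miR-374b-5p and miR-374c-5p in 2 each. Also for BYHWD, miR-450b-5p lost it in 25 of 28 and miR-21a-3p in 21 of 28, miR-199b-5p in 19, miR-31-5p in 18, miR-450a-5p in 16 and miR-379-5p in 9 of 29. Depth limits miR-10a-3p and miR-147-3p, at 1 to 3 and 1 to 4 counts per sham library, and also miR-21a-3p, at 6 to 14.

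The sign turned in 86 of these values, from 29 results that passed in neither setting, so none of their directions is firm. Median-ratio factors gave miR-150-5p -0.00675 for BYHWD versus sham. Upper-quartile factors gave miR-34b-5p 0.0225 for ICH versus sham, and miR-34c-5p -0.0355 for BYHWD versus ICH, and miR-150-5p -0.0216 for BYHWD versus sham. Library size alone gave miR-146b-5p 0.00302 and miR-34b-5p 0.0298 for ICH versus sham, and miR-126a-3p 0.0126 for BYHWD versus ICH, and miR-300-3p 0.12, miR-322-3p 0.16 and miR-486a-5p 0.0867 for BYHWD versus sham. No filter gave miR-34b-5p 0.0140 for ICH versus sham. The filter at 10 CPM gave miR-34b-5p 0.00735 for ICH versus sham, and miR-300-3p 0.00425 and miR-486a-5p 0.00156 for BYHWD versus sham. DESeq2 gave miR-150-5p -0.00720 for BYHWD versus sham. Limma-voom gave miR-34b-5p 0.0299 for ICH versus sham. Fits of 2 groups only gave miR-150-5p -0.00859 for BYHWD versus sham. Leaving out the 5 most abundant miRNAs gave miR-150-5p -0.0214 for BYHWD versus sham. Rows as deposited gave miR-143-3p -0.000902 for ICH versus sham, and miR-126a-3p 0.0375 for BYHWD versus ICH. Leaving out sham 4 and sham 5 gave miR-146b-5p 0.59, miR-150-5p -0.0758 and miR-219a-2-3p 0.30 for ICH versus sham. In the same fit the values were miR-146b-5p 0.42, miR-150-5p -0.19, miR-219a-2-3p 0.14, miR-322-3p 0.29, miR-34b-5p -0.0191 and miR-542-3p 0.25 for BYHWD versus sham. Quality weights gave miR-146b-5p 9.36e-05 and miR-34b-5p 0.18 for ICH versus sham, and miR-150-5p -0.0881 and miR-322-3p 0.0930 for BYHWD versus sham. Keeping names sharing reads once gave miR-150-5p -0.0237 for BYHWD versus sham. With 1 library left out, the ranges for ICH versus sham were miR-10b-5p -0.0801 to 0.33, miR-143-3p -0.13 to 0.26, miR-146b-5p -0.50 to 0.000644, miR-34b-5p -0.35 to 0.45 and miR-34c-5p -0.13 to 0.48. With 1 library left out, the ranges for BYHWD versus ICH were miR-126a-3p -0.11 to 0.0508, miR-143-3p -0.0476 to 0.21, miR-200a-3p -0.20 to 0.54, miR-204-5p -0.00247 to 0.39 and miR-34b-5p -7.95e-05 to 0.57. Others of this comparison were miR-34c-5p -0.19 to 0.33, miR-451a -0.27 to 0.81 and miR-486a-5p -0.0773 to 0.20. With 1 library left out, the ranges for BYHWD versus sham were miR-10b-5p -0.0679 to 0.38, miR-127-3p -0.0327 to 0.16, miR-143-3p -0.00799 to 0.39, miR-150-5p -0.12 to 0.0824 and miR-300-3p -0.0780 to 0.00484. Others of this comparison were miR-322-3p -0.22 to 0.0737, miR-34b-5p -0.0463 to 0.70, miR-381-3p -0.0221 to 0.22, miR-434-5p -0.29 to 0.0274 and miR-451a -1.04 to 0.33. Others of this comparison were miR-486a-5p -0.23 to 0.0284.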

Other observations

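Among the miRNAs whose values depended on sham 4 and sham 5 was miR-146a-5p, a brake on NF-kB signalling. Over all libraries its sham mean was 2831 CPM and its log2 fold change in ICH 0.85, and without sham 4 and sham 5 it was 1.62 (SE 0.17, edgeR adjusted p = 3.1e-05), and 1.14 in BYHWD (edgeR adjusted p = 0.0019). MiR-152-3p was called in the same fits (log2 1.24 in ICH and 1.14 in BYHWD, against 0.23 and 0.12 with all libraries), and miR-540-3p of the Dlk1-Dio3 cluster was lower (log2 -0.99 and -0.89). These fits were chosen after the data were seen.

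Some miRNAs, picked after their values were seen, were high in single libraries or ranged widely within 1 group. Their spread between animals was not tested against that between groups. The liver miRNA miR-122-5p was at 61.7 CPM in sham 1 and at 11.8 CPM or less in the other 14 libraries, and miR-451a was highest in the same library among the sham group (271 CPM). MiR-1298-5p, which lies in an intron of Htr2c, ranged from 883 to 15218 CPM within the sham group alone. MiR-200a-3p was at 214.3 CPM in BYHWD 4, the library with the highest miR-451a of its group.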
